A study of Mus musculus with 2 samples.

How the data were processed

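The data were 2 dye-swapped 2-colour Agilent arrays of ureters of mouse embryos at stage E14.5, each with 1 control RNA and 1 RNA labelled Gata2cKO. Per the labels, total RNA was extracted with a phenol-based reagent, amplified and coupled to Alexa Fluor 555 or 647 through amino allyl groups. On the array of replicate 1 (female) the control carried 555 and the Gata2cKO RNA 647, and on that of replicate 2 (male) the dyes were exchanged.

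Per the file headers, the authors scanned array design 026655 and read it with Agilent Feature Extraction 10.7.3.1 under protocol GE2_107_Sep09, with probe coordinates on mm9. The deposited scanner files give the mean spot signal and the median local background as intensity on a linear scale, with no normalization. They also give processed signals, which per the file headers the software had background-subtracted, detrended and dye-normalized by a linear step and a LOWESS curve, and a log10 ratio of red over green processed signal per the file headers. In the authors' deposited values there is 1 entry per probe and array, with 39429 probes. From its entries this table is a signed fold change with no value between -1 and 1, with a median of 1 in both columns and 28% and 28.3% of probes at exactly 1. How it was made and centred is not given in the sources used here, and its direction was taken from the sign of its correlation with the scanner ratios. Those correlations were only 0.361 and 0.277, so the table was used as an alternative alone, as a log2 of the fold with its sign.

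Each array held 44397 spots, of which 1224 positive and 153 negative controls were left out after background correction, leaving 43020 spots of 39429 probes. Spots with an outlier flag were left out (255 on array 1 and 178 on array 2). No spot was saturated (0 on both). The median local background was 34 and 70 on array 1 and 33.5 and 67.5 on array 2, for 555 and 647. Background was corrected by normexp with an offset of 50. Log ratios were normalized within each array by loess (span 0.3) with control and outlier spots at weight 0, array 2 was turned so that both run Gata2cKO over control, and spots of a probe were averaged. Probes were kept when well above background on both arrays in the control channel or on both in the Gata2cKO channel (25657 probes), and each gene was represented by its probe with the highest mean brightness (20506 genes). Probe accessions without versions were matched to the names in a RefSeq table of assembly GRCm38.p6, which named 26412 probes, and the other 13017 kept the name in the file. No coordinate of that assembly was used, and an mm9 gene annotation was not used here, so exons were not assigned.

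Ratios were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. With 2 arrays there was 1 residual degree of freedom per gene, and eBayes added a prior of 4.68 degrees of freedom with an SD of 0.163. A dye effect common to both arrays cancels in the mean and enters the SD. Sex and dye orientation cannot be told apart here, and neither was fitted. Both arrays lay on 1 slide, so the slide was no batch, and their number limits the precision. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated one), which compares a list with the other genes, and with fry, which does not, adjusted over the 22 lists. Of a list's genes, counts are also given adjusted over the list alone, and its median was set among 10000 random lists matched on brightness in 20 bins. A gene not well above background in both arrays of 1 group, of which 104 were tested, has only a bound. Its fold was taken against the higher of its own signal and the lowest signal well above background, per channel after loess and Aquantile. Files were read in R with jsonlite 2.0.0 and version 1.17.8 of data.table, and figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

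The genes named were fixed by a rule before the data were examined, as were the gene lists, the tests and most alternatives. The rule took Gata2, Tbx18 and the sex-linked genes, then the 12 genes with the largest ratio in each direction, ranked by the smaller of their ratios on the arrays among those at least 1.5-fold on both with the same sign, leaving out clones and predicted genes without a proper symbol. From each list it took members past the threshold, up to 4, or else the 2 with the largest ratios of the same sign, and for pathways the genes a reader looks for first. The value of 1 list member is not reported here. The words rose and fell are used of genes past an adjusted p, over all genes or, where said, adjusted over the list alone.

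The functions were tested on simulated arrays with the spots, dye curves and spread of this comparison, in 10 draws of 20506 genes with 200 changed genes each. An adjusted p under 0.05 was reached by 6.87% of genes changed 1.5-fold, 77.5% of those changed 2-fold and 99.7% of those changed 4-fold. Unchanged genes made up 9.07% of the 1345 calls (122), more than the nominal 5%, and 53 of 2000 unchanged lists had a camera p under 0.05. The simulated dye curve had the span of 0.3 that loess then removed, so dye bias left over in bright genes was not simulated. Noise was drawn independently for each probe, so these rates do not show how camera behaves with correlated genes.

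The alternatives were no background subtraction, the scanner software's processed signals, median centring, Aquantile with scaling between arrays, no detection filter, detection in all channels, the mean over a gene's probes, a trended and robust eBayes, the authors' deposited table, and each array alone. A loess span of 0.05, the counts outside the brightest 25% of genes and those without the listed neuron genes were added after seeing the data.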

Results

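Gene expression was measured in ureters dissected from NMRI mouse embryos at stage E14.5, with 2 dye-swapped 2-colour Agilent arrays. Each array held RNA labelled control in one dye and RNA labelled Gata2cKO in the other. Per the labels, the Gata2cKO embryos carried 1 Tbx18 allele that makes Cre recombinase, which acts in the mesenchyme around the ureter, and 2 loxP-flanked (floxed) alleles of Gata2, a zinc finger transcription factor. The control embryos had no Cre, at least 1 floxed Gata2 allele and a further allele that the label leaves open. Both RNAs were female on the array of replicate 1 and male on that of replicate 2. The Gata2cKO RNA carried Alexa Fluor 647 on the first array and 555 on the second, so sex and dye orientation changed together. The number of embryos behind each RNA is not given in the labels. The p-values of single genes rest on the spread between these 2 arrays and on a prior drawn from all genes. Camera with a preset correlation sets a list against the spread across genes. Its p-values therefore do not measure how far the arrays agree. The median spot signal was 433.1 (control) and 753.6 (Gata2cKO) on array 1, and 754 (control) and 428.1 (Gata2cKO) on array 2, so the 647 channel was brighter on both. Between 66% and 69.4% of the non-control spots were well above background in a channel, and 20506 genes were tested.

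The design asks which genes changed in the ureter when Gata2 is removed from cells with Tbx18-driven Cre. By the labels, Cre and the Tbx18 allele that carries it were present in the Gata2cKO embryos alone. Effects of either therefore cannot be told apart here from those of the loss of Gata2. Gata2 itself was not lower in the RNA labelled Gata2cKO. Its only probe gave log2 ratios of 0.33 on array 1 and 0.54 on array 2, a mean of 0.44 ± 0.153 (SD, n = 2; adjusted p = 0.409). This probe lies on chromosome 6 from 88156362 to 88156421 (mm9) and has the sequence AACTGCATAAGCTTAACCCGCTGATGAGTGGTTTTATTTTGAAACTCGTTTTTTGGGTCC. The labels do not say which part of Gata2 is deleted, and a probe outside the deleted part checks nothing. Tbx18, with 1 allele carrying Cre in the Gata2cKO, was not lower either (log2 ratio 0.40 ± 0.357, SD, n = 2; adjusted p = 0.66). Its values were 0.65 and 0.15 on the arrays. The targeted gene therefore does not check the label, and each direction given here rests on the dyes in the labels and is written for the RNA labelled Gata2cKO.

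The lists of smooth muscle genes and of neuron and glia genes were lower in the RNA labelled Gata2cKO by camera with a preset correlation (adjusted p = 0.533 with an estimated correlation for each), with 0 and 1 of their members passing an adjusted p of 0.05 over all genes. Sostdc1, which encodes a secreted antagonist of BMP and Wnt signalling, rose 4.16-fold (log2 ratio 2.06 ± 0.0580, SD, n = 2; adjusted p = 0.0209). The serotonin receptor gene Htr2b rose 3.03-fold (log2 ratio 1.60 ± 0.205, SD, n = 2; adjusted p = 0.0380), and the vasopressin receptor gene Avpr1a rose 2.83-fold (SD of the log2 ratio 0.275, n = 2; adjusted p = 0.0490). Chgb, which encodes a protein of neuroendocrine secretory granules, fell (log2 ratio -2.06 ± 0.339, SD, n = 2; adjusted p = 0.0380), as did Prph, an intermediate filament gene of peripheral neurons (log2 ratio -1.35 ± 0.0465, SD, n = 2; adjusted p = 0.0380). In the authors' deposited table Chgb was at -0.02 in the column for array 1 and -2.46 in that for array 2, and Prph at -0.72 and -0.80.

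Of the 20506 genes tested with limma, 18 passed an adjusted p of 0.05, 9 higher and 9 lower in the RNA labelled Gata2cKO, each in the same direction on both arrays. The other genes that rose were the RNA helicase gene Ddx6 (log2 ratio 2.16), the ciliary neurotrophic factor receptor gene Cntfr (1.54), Lrriq1 (2.82-fold), C920006O11Rik (1.47), the potassium channel interacting protein gene Kcnip1 (1.34) and the homeobox gene Alx1 (1.31). In the authors' deposited table the means for Ddx6 and Cntfr had the opposite sign, at log2 ratios of -0.20 and -0.13. Its column for array 1 gave 0.01 for Slc18a2 and 0.04 for Dbh, both named below, and that for array 2 gave -1.82 and -1.65. The other Cntfr probe gave 0.28 and 0.02 on the arrays, while both Sostdc1 probes lay above 2. The other genes that fell were Higd1c (log2 ratio -1.90), Methig1 (-1.69), the secreted C1q-like gene C1ql3 (-1.58), the neuronal catenin gene Ctnna2 (-1.50), the vesicular monoamine transporter gene Slc18a2 (-1.36), Colq (-1.31), which encodes the collagen tail of acetylcholinesterase, and C2cd4b (-1.27). The other Colq probe gave -0.19 and -0.42 on the arrays, the other Ctnna2 probe -1.14 and -0.60, and the other Slc18a2 probe, not well above background in the RNA labelled Gata2cKO, -0.58 and -0.53. Over the mean of a gene's probes Cntfr (adjusted p = 0.0772), Ctnna2 and Slc18a2 (0.0646 each) and Colq (0.0791) did not pass. C920006O11Rik and C2cd4b lay outside the rule for named genes and were chosen after their values were seen. Dach2 (1.15, adjusted p = 0.0503), Acsl1 (1.05, adjusted p = 0.0532), Neto2 (1.04, adjusted p = 0.0532) and Fzd10 (1.09, adjusted p = 0.0714) were among the largest positive ratios and did not pass. The same held among the negative ratios for the retinoic acid degrading enzyme gene Cyp26a1 (-2.02, adjusted p = 0.0503), the chromogranin gene Chga (-1.88, adjusted p = 0.0505), the noradrenaline synthesis gene Dbh (-1.68, adjusted p = 0.0732) and the neuroendocrine transcription factor gene Insm1 (-1.43, adjusted p = 0.0503). Median centring in place of loess, and the authors' deposited table, each left 0 genes past the threshold by limma, with 492 and 972 at an unadjusted p under 0.05, against 1470. With a trended and robust variance 376 genes passed, the 18 among them.

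**Figure D1:**
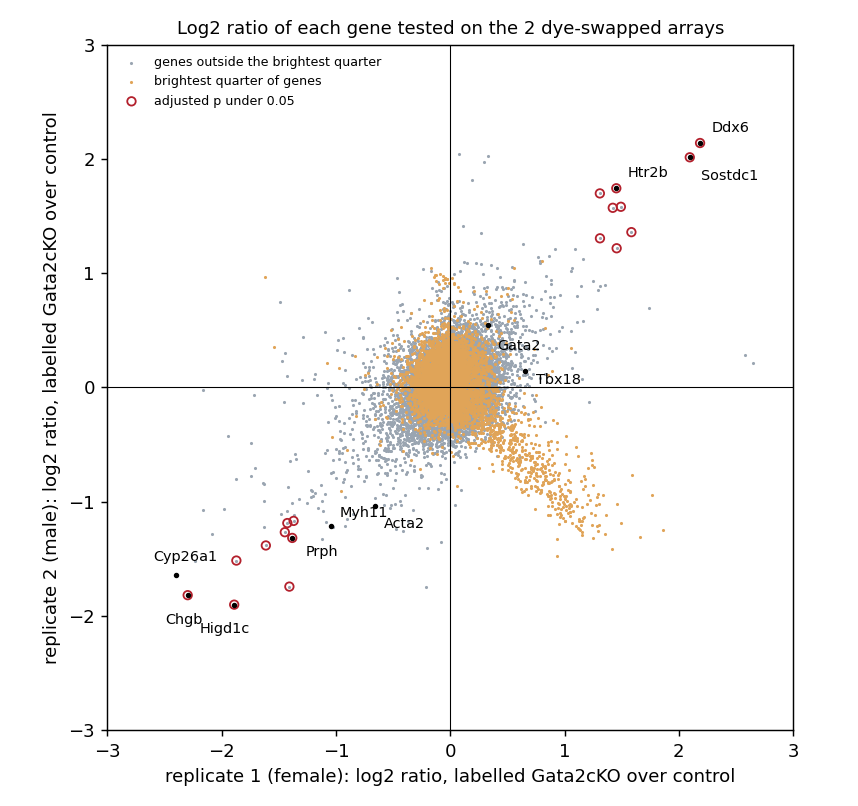
Log2 ratio of the RNA labelled Gata2cKO over control for each of the 20506 genes tested, on the female array (x axis) against the male array (y axis), with genes of the brightest 25% in orange and genes past adjusted p 0.05 circled. Of the 240 genes at least 1.5-fold with opposite signs on the arrays, 236 lie in the orange group, and the 18 circled genes lie at the upper right and lower left.

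By size alone, 146 genes differed at least 1.5-fold with the same sign on both arrays, 56 higher and 90 lower, and 39 differed at least 2-fold, 13 higher and 26 lower. On array 1 alone more genes were higher than lower at 1.5-fold (428 and 280), and on array 2 alone fewer (272 and 429). More genes were as large with opposite signs, 240 at 1.5-fold and 48 at 2-fold. Of the 240, 236 were brighter in the 647 channel on both arrays and 236 lay among the brightest 25% of genes, the group in which the arrays correlated at r = -0.572. Among the 15379 genes outside that group, 142 had the same sign at 1.5-fold (54 higher, 88 lower) and 4 had opposite signs. Across all genes, which are not independent replicates, Pearson's r of the arrays was 0.0643 and Spearman's rho 0.0956. In the brightest 10253 genes they were -0.26 and -0.0467, and outside the brightest 25% they were 0.389 and 0.238. The split of the 1.5-fold genes, 56 higher and 90 lower, was 152 and 134 with the scanner software's processed signals and 209 and 184 in the authors' deposited table. With median centring it was 59 and 90, and with Aquantile 57 and 88.

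Genes were then grouped by 22 lists fixed before the data were examined, of which 11 differed from the other genes by camera with a preset correlation of 0.01. No list passed with an estimated correlation (the lowest adjusted p = 0.533 with an estimated correlation). With 2 arrays that test has 1 residual degree of freedom, so it could pass hardly any list. The macrophage list, with an estimated correlation of -0.0667, went from a camera p of 2.15e-11 to 0.0884. A call lost there does not by itself show that correlated genes undid it. The estimated correlation was 0.559 for the neuron and glia list, 1 for skeletal muscle, 0.138 for urothelium and 0.0154 for smooth muscle. With 1 residual degree of freedom these estimates are rough. Where they lie far above the preset of 0.01, the p-values with the preset correlation may be far too small. By fry, which asks whether a list's genes move one way on balance and compares them with no other genes, no list passed either. Among 10000 random lists matched on brightness, the medians of the smooth muscle, neuron and glia, macrophage, skeletal muscle and fibroblast lists lay at percentile 0, and those of the ureteric mesenchyme and urothelium lists at percentile 100. Random lists do not keep the correlation among the genes of a list, and the percentile does not measure how far the arrays agree. The fibroblast list had medians of 0.00655 and -0.26 on the arrays. Uncalled lists also lay far out, such as erythroid (0.15) and hedgehog (0.67).

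Smooth muscle genes were lower as a group. Of 26 tested, 15 were lower and 1 was higher on both arrays, with a median log2 ratio of -0.168 (camera adjusted p = 1.2e-08; adjusted p = 0.533 with an estimated correlation). Over all genes tested 0 members rose or fell. Adjusted over the list alone, 9 fell and 1 rose. Those that fell by that count included the smooth muscle myosin gene Myh11 (-1.13 ± 0.118, SD, n = 2; adjusted p = 0.0509 over all genes), the actin genes Actg2 (-1.13 ± 0.139; adjusted p = 0.0532) and Acta2 (-0.85 ± 0.266; adjusted p = 0.155), Tagln (-0.49 ± 0.313, with -0.268 on array 1 and -0.7111 on array 2; adjusted p = 0.462) and Myocd, the coactivator that drives this programme (-0.69 ± 0.0813; adjusted p = 0.155). The 1 member that rose by that count was Pgm5 (0.37). Myocd had the opposite sign in the authors' deposited table (0.16). Skeletal muscle genes were also lower (12 tested, median -0.39, with -0.178 on array 1, -0.548 on array 2 and -0.209 with no filter on detection; camera adjusted p = 1.93e-08; adjusted p = 0.533 with an estimated correlation), with 0 members passing over all genes and 5 falling adjusted over the list alone. Among them were the actin gene Acta1 (-0.79 ± 0.3699, SD, n = 2) and the embryonic myosin gene Myh3 (-0.86 ± 0.5417), the latter at -0.472 on array 1 and -1.238 on array 2.

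Genes of neurons and glia had the lowest median of the 22 lists. Of 17 genes tested, 16 were lower on both arrays, with medians of -0.964 on array 1 and -0.66 on array 2 and a median log2 ratio of -0.759 (camera adjusted p = 5.07e-26; adjusted p = 0.533 with an estimated correlation). Prph fell over all genes tested, and 16 members fell adjusted over the list alone. They included Th and Dbh, enzymes of catecholamine synthesis (-1.26 and -1.68), the autonomic neuron regulator Phox2a (-1.31) and the glial factor gene Sox10 (-0.63). These examples beyond Prph and Dbh were chosen after their values were seen. Macrophage and immune genes were lower too (15 tested, 13 lower on both arrays, median -0.321; camera adjusted p = 2.37e-10; adjusted p = 0.533 with an estimated correlation). None passed over all genes, and 3 complement genes fell adjusted over the list alone, among them C1qa (-0.59) and C1qc (-0.44). Endothelial genes had a median of -0.0957 over 14 genes (-0.159 on array 1 and -0.0716 on array 2), with Plvap at -0.31 and Cldn5 at -0.19 (camera adjusted p = 0.0426; adjusted p = 0.533 with an estimated correlation), and 0 passed over all genes or over the list alone. The call was lost with the scanner software's processed signals (camera adjusted p = 0.0764), with median centring (0.0551) and over probe means (0.0735), and in the authors' deposited table the median was positive (0.103). A count added after the values were seen left out the genes of the neuron and glia list and of a further neuron list given below. In it 13 genes passed an adjusted p of 0.05 (7 higher, 6 lower) and 135 were at least 1.5-fold (56 higher, 79 lower). Nerve and chromaffin genes in neither list, such as Chgb, Chga, Slc18a2, Insm1 and Npy, stayed in, so that signal was removed only in part. The smooth muscle list, whose own genes were not removed, kept its call (camera adjusted p = 1.29e-08; adjusted p = 0.533 with an estimated correlation over all genes).

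**Figure D2:**
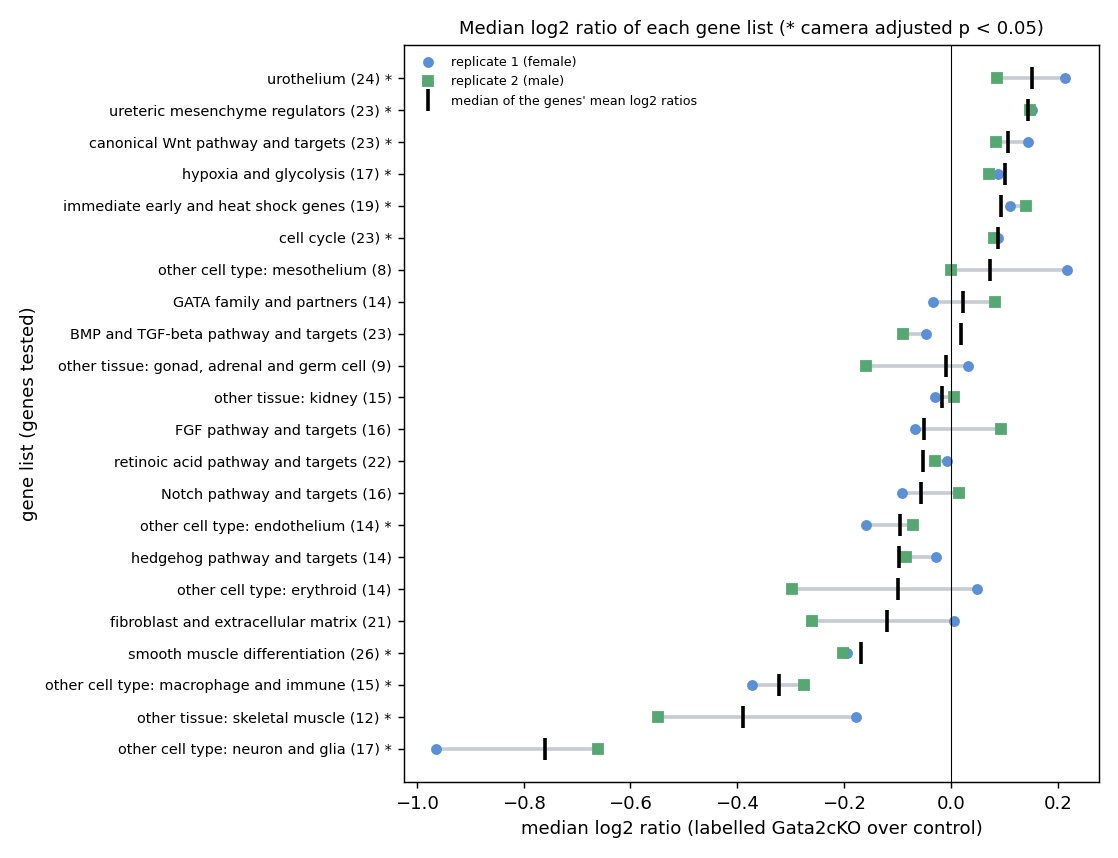
Median log2 ratio (x axis) of each of the 22 gene lists (y axis, with the number of genes tested) on the female array (circles), on the male array (squares) and over the genes' mean ratios (bars), with an asterisk at a camera adjusted p under 0.05. The asterisks are for the preset correlation, and no list passed with an estimated one, a test with 1 residual degree of freedom. The neuron and glia list lies lowest at -0.759, and the urothelium list highest at 0.151, although its median was negative in the authors' deposited table (-0.263).

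Urothelial genes, which mark the epithelium of the ureter, were higher as a group with loess and lower in the authors' deposited table. Of 24 tested, 15 were higher and 0 lower on both arrays, with a median of 0.151 and medians of 0.213 on array 1 and 0.0861 on array 2 (camera adjusted p = 0.000198; adjusted p = 0.533 with an estimated correlation). The deposited table gave a median of -0.263 and a camera adjusted p of 9.99e-05 in the opposite direction. None passed over all genes, and the tight junction gene Cldn4 alone rose adjusted over the list alone (0.87, with 1.158 on array 1 and 0.5787 on array 2; -0.56 in the authors' deposited table). Upk1b was at 0.33, Upk3a, another gene of the urothelial plaque, at 0.51 ± 0.526 (SD, n = 2), and the ligand gene Shh at 0.17 ± 0.388. Mesothelial genes did not pass as a list (8 tested, median 0.0727, with 0.217 on array 1, 2.84e-06 on array 2 and -0.0199 in the authors' deposited table; camera adjusted p = 0.0872), with Msln at 0.28, Krt19, also a urothelial gene, at 0.05 and 0 members passing by either adjustment.

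Regulators of the ureteric mesenchyme were higher as a group (23 tested, 12 higher and 5 lower on both arrays, median 0.144; camera adjusted p = 0.034; adjusted p = 0.533 with an estimated correlation). None passed singly by either adjustment. Tshz3, a factor needed for ureteric smooth muscle, was at 0.52 ± 0.118 (SD, n = 2) and Id4 at 0.44 ± 0.0679. The list lost its call with median centring and with the scanner software's processed signals (camera adjusted p = 0.153 and 0.112). The list of the GATA family and its partners did not pass (14 tested, median 0.0224, with -0.0337 on array 1 and 0.0826 on array 2; camera adjusted p = 0.912, in the opposite direction with median centring), with 0 passing by either adjustment and the partner gene Zfpm1 at -0.24.

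Among signalling pathways, the canonical Wnt list was higher (23 tested, 12 higher and 4 lower on both arrays, median 0.106; camera adjusted p = 0.0378; adjusted p = 0.533 with an estimated correlation). It had 0 members passing by either adjustment, with the secreted inhibitor gene Wif1 at 0.78, the feedback inhibitor gene Nkd1 at 0.46 and the target gene Axin2 at -0.04. The call was lost with the scanner software's processed signals (camera adjusted p = 0.0764). Retinoic acid genes went both ways. Of 22 tested, none passed over all genes, and adjusted over the list alone 3 rose, among them the synthesis gene Aldh1a3 (0.84; -0.20 in the authors' deposited table), and Cyp26a1 fell. Aldh1a2, also a synthesis gene, was at 0.29 and the receptor gene Rarb at 0.27. The median and mean of this list were negative (-0.0523 and -0.0162) and its camera direction was up (adjusted p = 0.794), or down with the scanner software's processed signals. Its median was -0.00741 on array 1 and -0.0292 on array 2, and 0.0128 in the authors' deposited table. The BMP and TGF-beta list had a median of 0.0189, though -0.0467 on array 1 and -0.0889 on array 2, a negative mean (-0.0527) and a downward camera direction (23 tested; adjusted p = 0.444) that was upward in the authors' deposited table. Adjusted over that list alone 2 rose, among them the BMP antagonist gene Grem1 (0.66), and 3 fell, among them Inhba (-0.55), while Bmp4 was at 0.15 and Id2 at 0.03. The FGF list did not pass (16 tested, median -0.0497, with -0.0667 on array 1 and 0.0935 on array 2; camera adjusted p = 0.363, but 0.00204 in the authors' deposited table with a median of -0.187), although 3 members fell adjusted over the list alone, among them Etv1 (-0.77) and the growth factor gene Fgf7 (-0.61). In the hedgehog list (14 tested, median -0.0969, with -0.0279 on array 1 and -0.0836 on array 2; camera adjusted p = 0.444) Foxl1, a factor downstream of the pathway, rose adjusted over the list alone (0.68), with the target genes Hhip at -0.35, Ptch1 at -0.08 and Gli1 at 0.12. In the authors' deposited table this list was higher, with a median of 0.119 (camera adjusted p = 0.0265). The Notch list did not pass (16 tested, median -0.0556, with -0.0921 on array 1, 0.0148 on array 2 and 0.0813 in the authors' deposited table; camera adjusted p = 0.907, direction up by fry and with detection in all channels), with Hey2 at 0.48, Hes1 at -0.31 and 0 members passing by either adjustment.

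Cell cycle genes were slightly higher (23 tested, 14 higher and 1 lower on both arrays, median 0.0879; camera adjusted p = 0.0426; adjusted p = 0.533 with an estimated correlation), with Ccna2 at 0.29 and Bub1 at 0.22. Immediate early and heat shock genes were higher (19 tested, median 0.0939, with 0.11 on array 1 and 0.141 on array 2; camera adjusted p = 0.0335; adjusted p = 0.533 with an estimated correlation), with Egr1 at 0.48 and Nr4a1 at 0.38, and had a median of -0.0617 in the authors' deposited table. Hypoxia and glycolysis genes were higher (17 tested, median 0.102; camera adjusted p = 0.0439; adjusted p = 0.533 with an estimated correlation), with Hk2 at 0.28 and Egln3 at 0.17. Each of these lists had 0 members passing by either adjustment and lost its call with median centring, with the scanner software's processed signals and in the authors' deposited table, and those of the cell cycle and hypoxia also with the narrower loess span. Fibroblast and extracellular matrix genes (21 tested, median -0.119, with 0.00655 on array 1 and -0.26 on array 2; camera adjusted p = 0.0774), with Dpt at -0.47 and Vcan at 0.46, and erythroid genes (14 tested, median -0.0998, with 0.0491 on array 1 and -0.298 on array 2; camera adjusted p = 0.139), with Hbb-bh1 at -0.33 and Hemgn at 0.19, did not pass, and 0 members did by either adjustment. The fibroblast list passed as lower with processed signals (camera adjusted p = 0.0409), no filter on detection (0.0498) and the narrower loess span (0.0382). The kidney list did not pass (15 tested, median -0.0164, with -0.0294 on array 1 and 0.00501 on array 2; camera adjusted p = 0.742, but 0.0120 in the authors' deposited table with a median of -0.199), with Wnt11 (-0.61), Crym (-0.56) and Ret, which the neuron list also holds, falling adjusted over the list alone. The gonad, adrenal and germ cell list did not pass (9 tested, median -0.00991, with 0.0322 on array 1 and -0.16 on array 2; camera adjusted p = 0.158). Its gene Lhx9 was not well above background in the RNA labelled Gata2cKO and was at least 1.49-fold higher in the control (adjusted p = 0.218), and fell adjusted over the list alone, while the adrenal gene Cyp21a1 was at -0.14. Besides the genes for which this is given, Insm1, Ptch1, Axin2, Id2, Shh, Hhip, Upk1b, Krt19, Plvap and Nr4a1 had the opposite sign in the authors' deposited table.

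Sex-linked transcripts were compared with the labels by brightness. The brighter Xist probe had 163 times the background in the female control, 173 times in the female RNA labelled Gata2cKO, and 1.83 and 1.53 times in the male control and Gata2cKO RNA. Of 20 calls over Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in the 4 channels, 16 were as the labels say when signal above 2 times the background counted as present, a threshold chosen after the values were seen. With the scanner's own detection flags 17 were. Ddx3y was at 130 times the background in the male control, 1.52 times in the female control and 9.92 times in the female RNA labelled Gata2cKO, and Eif2s3y at 142, 2.18 and 13.7 times.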

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

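The comparison with the brightest genes and the threshold for Y-linked signal were chosen only after the results were seen, and no difference between the arrays described here was tested, since each sex was on 1 array and in 1 dye orientation.

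At least 1.5-fold ratios of opposite sign on the female and the male array were found for 240 genes, against 146 with the same sign. The 647 channel was the brighter on both arrays for 236 of them, and 236 lay in the brightest 25% of genes. With a loess span of 0.05, chosen after seeing the data, 29 such genes were left, so most of this count goes with the span of the curve.

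For 7 gene lists the median log2 ratio had opposite signs on the female and the male array, and the differences were not tested. Female minus male, they were 0.347 for erythroid genes, 0.267 for fibroblast and matrix genes, 0.192 for gonad, adrenal and germ cell genes, -0.16 for the FGF list, -0.116 for the GATA list, -0.107 for the Notch list and -0.0344 for kidney genes. None of these lists passed camera in the comparison.

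For 6 of the named genes the 2 arrays had opposite signs, also untested. Female minus male log2 ratios were 0.549 for Shh, 0.538 for Ptch1, 0.246 for Id2, -0.261 for Axin2, -0.536 for Rarb and -0.621 for Aldh1a2. The female ratio was close to 0 for the last 2, at -0.003 for Rarb and -0.0156 for Aldh1a2. Another probe, well above background, had the same sign on both arrays for Rarb (0.1095 female, 0.1189 male) and for Ptch1 (0.2007 female, 0.3138 male).

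Y-linked signal was present in a channel labelled female. In the female RNA labelled Gata2cKO, Ddx3y had 6.54% and Eif2s3y 7.59% of the net signal of the male control in the same dye, and both were well above background. In the female control neither was. Kdm5d and Uty, dim in the male channels too, were not well above background in either female channel. What gave this signal was not tested.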

How the results depend on the processing

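Results under a loess span of 0.05, outside the brightest 25% of genes and without the listed neuron genes were chosen after seeing the data. The other alternatives were chosen before the data were examined. Gata2 (0.37 to 0.58, adjusted p 0.169 to 1) and Tbx18 (0.38 to 0.51, adjusted p 0.221 to 1) stayed positive and did not pass in any of the 10 refitted settings. The smooth muscle, neuron and glia, macrophage and skeletal muscle lists kept their direction and camera call in these 10, and all lost it with an estimated correlation. None passed by fry, which compares a list with no other genes. Both tests rest on 1 residual degree of freedom here, which makes it hard for a list to pass. By fry the ureteric mesenchyme list still came to a p of 0.00262 (adjusted p = 0.0576), so small p-values were within reach of fry. Of the comparisons of single named genes with their reported value in these 10, 615 kept direction and side of the threshold, 78 newly passed, 47 no longer passed and 19 reversed. Each array alone leaves no residual degrees of freedom, so no test, correlation or list test was made there, and 6 of the 76 named genes other than Gata2 and Tbx18 had opposite signs on the arrays. Unless a cause is given, the cause was not tested. Signal over background limits the dimmest genes, and further arrays would be needed to separate sex from dye. No paired analysis was possible because each ratio already lies within 1 array.

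Against 18 genes past an adjusted p of 0.05, 3 passed with no background subtraction (2 higher, 1 lower), 129 with the scanner's processed signals (59, 70), 0 with median centring (492 at an unadjusted p under 0.05), 54 with no detection filter (18, 36), 35 with detection in all channels (13, 22), 376 with trended and robust eBayes (167, 209), 0 in the authors' deposited table (972 unadjusted) and 153 with the narrower span (62, 91). All 18 were among those of the processed signals, no filter, strict detection, eBayes and narrower span settings. At an adjusted p under 0.1 there were 75, and at an unadjusted p under 0.05 there were 1470.

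Against 146 genes at least 1.5-fold and 39 at least 2-fold on both arrays, the processed signals gave 286 (152 higher, 134 lower) and 79, and the authors' deposited values 393 (209, 184) and 114. A single array, which need not pass on a second, gave 701 to 708 and 151 to 194, and the split turned, with 428 higher and 280 lower (2-fold 114 and 80) on array 1 and 272 and 429 (38 and 113) on array 2. The correlation of the arrays (0.0643) was 0.298 with processed signals, -0.384 with median centring, 0.0212 with no filter, 0.0467 with strict detection, 0.0892 over probe means, -0.00733 in the deposited table, 0.274 with the narrower span and 0.389 outside the brightest 25% of genes.

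Single genes reversed as follows. Axin2 was at 0.029 with processed signals, Id2 at -0.043 and Krt19 at -0.033 with median centring, and Ptch1 at 0.090 over probe means. In the deposited table Ddx6 was at -0.20, Cntfr -0.13, Insm1 0.077, Myocd 0.16, Ptch1 0.93, Axin2 0.94, Id2 -0.28, Shh -0.44, Aldh1a3 -0.20, Hhip 0.046, Cldn4 -0.56, Upk1b -0.015, Krt19 -0.00058, Plvap 0.016 and Nr4a1 -0.058.

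Camera called 11 lists, and 6 with processed signals (the fibroblast list among them, not 1 of the 11), 6 with median centring and 0 with an estimated correlation. Fry, which asks another question, called 0. With processed signals the adjusted p was 0.112 for mesenchyme regulators and cell cycle, 0.0764 for Wnt, endothelium, immediate early genes and hypoxia, 0.0409 for fibroblast genes (newly called) and 0.984 for retinoic acid (reversed). With median centring it was 0.153 for mesenchyme regulators, 0.112 for cell cycle, 0.0551 for endothelium, 0.0690 for immediate early genes, 0.154 for hypoxia and 0.971 for the GATA list (reversed). Fibroblast genes were called with no filter (0.0498) and the narrower span (0.0382), where cell cycle and hypoxia (0.0533 each) were not. Notch reversed with strict detection (0.999), endothelium lost its call over probe means (0.0735), and the kidney list reversed without the neuron genes (0.905), where Ret leaves it. In the deposited table the lists for hedgehog (0.0265), BMP and TGF-beta (0.825), Notch (0.923), urothelium (9.99e-05), endothelium (0.269) and immediate early genes (0.146) reversed, FGF (0.00204) and kidney (0.0120) newly passed, and cell cycle (0.142) and hypoxia (0.181) did not pass. With an estimated correlation all 11 called lists, those of smooth muscle, mesenchyme regulators, Wnt, urothelium, cell cycle, endothelium, macrophage, neuron and glia, skeletal muscle, immediate early genes and hypoxia, had an adjusted p of 0.533. By fry it was 0.370 for smooth muscle and neuron and glia, 0.0576 for mesenchyme regulators, 0.498 for Wnt, urothelium, skeletal muscle and hypoxia, 0.267 for cell cycle, 0.587 for endothelium, 0.206 for macrophage, 0.280 for immediate early genes and 0.969 for Notch (reversed).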

Other observations

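The genes in these first paragraphs were chosen after their values were seen, from the 146 that were at least 1.5-fold with the same sign on both arrays, and none of them passed an adjusted p of 0.05 over all genes, except the 4 genes with neighbouring probes, which passed and were named by the rule. No group of genes with a shared role was tested from them. Lower in the RNA labelled Gata2cKO were Npy, a peptide of sympathetic neurons (log2 ratio -1.52 ± 0.644, SD, n = 2), the granule genes Resp18 (-1.30 ± 0.269), Scg5 (-1.06 ± 0.0890) and Vgf (-0.99 ± 0.192), the monoamine transporter gene Slc18a1 (-1.14 ± 0.389), the acetylcholine transporter gene Slc18a3 (-0.90 ± 0.214), and Calca (-1.03 ± 0.178). The neurofilament genes Nefl (-1.09) and Ina (-1.13) were lower as well. So were Epyc (-1.22 ± 0.148, adjusted p = 0.0503), Col9a1 (-0.93 ± 0.0297) and Aspn (-0.73 ± 0.165), and the transcription factor genes Pitx1 (-1.24 ± 0.180, adjusted p = 0.0503) and Prdm6 (-0.76 ± 0.0211), the latter expressed in smooth muscle.

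Among the higher genes were Kcnma1 (1.10 ± 0.296), Kcnd3 (1.01 ± 0.199) and Kcnk2 (0.71 ± 0.133, all SD, n = 2). The natriuretic peptide clearance receptor gene Npr3 (0.91 ± 0.0971) was higher and the gene of the natriuretic peptide Nppc (-0.65 ± 0.0336) lower. The aryl hydrocarbon receptor gene Ahr was at 0.96 ± 0.214 and the laminin gene Lamc3 at 0.85 ± 0.0774. A pair of genes among those that rose and a pair among those that fell have neighbouring probes: Alx1 at 102471172 and Lrriq1 at 102531554 on chromosome 10, and Higd1c at 100214327 and Methig1 at 100214807 on chromosome 15 (mm9). Each pair moved in one direction, and a transcript read by both probes of a pair was not tested for.

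Of the tests that follow, only that of the further neuron genes had its outcome set before its result was seen, and the others were chosen after it.

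Gata2 and Tbx18 were not lower in the RNA labelled Gata2cKO. With the dyes of 1 array exchanged in the labels, changed genes would have opposite signs on the arrays. Of all genes at least 1.5-fold on both arrays 37.8% had the same sign with loess and 78.1% with the scanner software's processed signals, so the bounds set for this decided nothing. With the narrower loess span 83.5% had the same sign. Outside the brightest 25% of genes, a limit chosen after the opposite signs were seen, 142 had the same sign and 4 opposite signs. These genes argue against an exchange on 1 array. Of the 240 genes with opposite signs 236 lay in the brightest 25%, where the signs do not decide. An exchange on both arrays stays open. Gata2, at 0.436, would then be lower, but without the place of the deleted part it is not known what its probe should show, and the sex labels, alike within an array, do not separate the channels. A Gata2 probe outside the deleted part also stays open, with 1 probe on the array and no statement of that part in the labels. A transcript that is still made from the deleted allele, or raised in cells without Cre, was not tested.

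Nerve and chromaffin genes were lower in the RNA labelled Gata2cKO on both arrays. Adrenal tissue with its cortex in the control RNA is argued against by 10 steroid genes with a median of -0.0663, and the 6 of them made mainly in the cortex lay between -0.176 and 0.0893. Most of these 6 were dim. Of the 5126 genes in the dimmest 25%, 39 were at least 1.5-fold lower on both arrays, so a fall could be measured among dim genes. How large a fall these 6 could have shown was not tested, which limits the argument. More nerve and chromaffin cells in the control RNA may account for the lower genes, but a further list of neuron and granule genes, written before they were looked at, gave a median of -0.305, between the bounds of -0.4 and -0.2 set for it. Its medians were -0.478 on array 1 and -0.175 on array 2, each past a different bound, and -0.157 and -0.159 in the authors' deposited table. Of 18 genes, 12 were lower on both arrays, among them Cartpt (-1.742 on array 1 and -0.7724 on array 2), Nefm (-1.946 on array 1 and -0.421 on array 2) and Slc6a2 (at least 1.96-fold lower), and others such as Snap25 (0.24) and Syt4 (0.36) were higher. The median stayed at -0.305 with 2 genes that were not well above background in the RNA labelled Gata2cKO set to their bounds. Both lie below the median with either value, so this could not have moved it. Fewer nerve cells within the ureter of the genotype itself cannot be told apart from a difference in the pieces dissected, and in the authors' deposited table the neuron and glia list had medians of -0.324 and -0.765. Which of the explanations left open holds was not decided, and the smooth muscle, skeletal muscle and macrophage lists were lower in the same RNA by camera with a preset correlation (adjusted p = 0.533 with an estimated correlation for each).

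The authors' deposited table did not follow the scanner values of the same arrays. For another background correction or normalization of these scans, smooth functions of the 4 channel signals gave an R squared of at most 0.302. That fit took in all probes, also those not well above background, and what a known normalization would reach in it was not tested. It therefore does not decide. Over probes well above background the columns correlated with their own arrays at 0.486 and 0.382. Exchanged columns are argued against by a correlation of at most 0.196 with the other array against 0.361 and 0.277 with its own. Rows shifted by up to 100 against the probe names gave at most 0.0164. What remains is untested, and may include values from other scans or further arrays, given that 124 of the 146 genes at least 1.5-fold on both arrays had the same sign in both columns. No biological explanation was tested for this.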
